A study of Caenorhabditis elegans with 8 samples.

How the data were processed

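Chromatin immunoprecipitation with sequencing was done by the authors on whole C. elegans grown at 20°C, per the labels' protocols, with wild-type SKN-1 or the gain-of-function form SKN-1gf(lax188), each tagged with GFP. Pellets were ground and crosslinked with formaldehyde, and libraries were made with a Diagenode MicroPlex kit, per the labels' protocols. Samples were grouped by their titles and genotype labels into 4 groups of 2: WT and GF with antibody, and WT and GF without antibody. The 4 samples without antibody come with no file and were not analysed here.

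The authors deposited 1 peak list per precipitated sample in narrowPeak format, so peaks were called per sample and not on pooled samples. Trim Galore 0.6.4, BWA 0.7.17, SAMtools 1.10, MACS2 2.2.7.1 and genome build ce10 are named in the submitters' processing notes, without their settings. Which control MACS2 used, and whether it was the sample without antibody, is not given in the sources used here. Each deposited list gives a fold enrichment per peak (a ratio over the caller's background), a -log10 p and a -log10 q, and a whole-number score that equals about 10 times the deposited -log10 q. The lowest -log10 q was 1.3 in each deposited list, which is a q of 0.05. The lists carry no read counts, so the depth per library is unknown, and list length moves with depth and enrichment as well as with binding. Intervals on shares of peaks cover counting error over peaks only. Fold values were used to describe, rank and filter peaks within a list.

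Peaks were compared with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and drawn with matplotlib 3.10.9. Overlap meant at least 1 shared bp. Reproducible peaks were those of the shorter list of a genotype that overlapped the other list. Chance overlap came from 100 placements of each peak at a random position of its own chromosome. Lists were also shortened to 905 peaks, the length of the shortest, by fold, and compared by the Jaccard index, with an exact permutation over the 3 splits of the 4 lists. The 4 lists were merged into regions by overlap.

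Gene names came from a RefSeq gene table of assembly WBcel235, which is not the build named for the lists, and no position from that table is given. Short peaks (under 450 bp) at short tRNA, snRNA and snoRNA genes (under 250 bp) lay at a median offset from the table's genes of -29.5 bp in WT 1 (bootstrap 95% interval -79.5 to 24), -19 bp in WT 2 (-35 to 17), -2.0 bp in GF 1 (-11.5 to 10.5) and -7.75 bp in GF 2 (-46.25 to 40.25) on the far part of the chromosomes, where shifts between builds add up. Only peaks within 150 bp of a gene were taken (37, 79, 140 and 32 genes in that order), so a larger shift could not have shown. The check therefore does not establish that the builds agree. The table was used to tell which genes lie next to a peak, and each gene test was repeated with summits moved by 100 bp in either direction. The table has no strand and no transcripts, so the planned windows at transcript starts were replaced by windows of 1000 bp outside to 200 bp inside at either end of a protein-coding gene, and a gene with a summit in a window is called bound. The planned search for the SKN-1 motif needs a genome of the lists' build and was not run.

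Gene groups were fixed before the data were examined: 15 by gene name (phase II detoxification and glutathione, antioxidant enzymes, proteasome subunits, heat shock and unfolded protein response, lipid metabolism, SKN-1 regulation and signalling, RNA interference and antiviral, innate immune response, intestine markers, cuticle collagens and hypodermis, muscle structure, germline markers, sensory neurons including ASI, pan-neuronal genes, mitochondrial respiratory chain) and 8 by name pattern (cytosolic ribosomal proteins, chemoreceptors, glutathione S-transferases, UDP-glucuronosyltransferases, cytochrome P450, C-type lectins, histones, nuclear hormone receptors). Of 2757 names, 2751 matched the table. Each group was tested in each list, and in the genes bound in both lists of a genotype, with a two-sided Fisher exact test against all other protein-coding genes of the 6 nuclear chromosomes, adjusted by Benjamini-Hochberg over 138 tests. Single lists shortened to equal length were set against each other with exact McNemar tests on the genes of a group, also adjusted over 138 tests. On simulated data made from each of the 4 lists, 0 groups were called when peaks were placed at random, and 24 of 24 genes given a peak were found, with their group called. The random places ignored which parts of the genome real peaks favour. This checks the method and gives no rate of false calls for the deposited lists.

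The rule for named genes, fixed before the data were examined, took the 12 merged regions of all 4 lists with the smallest sum of ranks by fold, the 10 regions in both lists of a genotype and none of the other with the largest mean fold, up to 4 members of each gene group bound in all 4 lists or in both lists of 1 genotype only, and 8 genes in any case (skn-1, wdr-23, gst-4, gcs-1, gst-10, drh-1, dcr-1 and daf-7). Regions needed a protein-coding gene in a window. Alternatives were a -log10 q of at least 5 or 10, other overlap rules, other windows, the nearest gene end, equal list lengths, each list left out in turn, and pairing of lists with the same replicate number. Added after the data were seen were whole genes tested within 10 classes of gene length by a Cochran-Mantel-Haenszel test, shifted summits, and the strongest 5000 peaks of the 3 long lists.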

Results

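Chromatin immunoprecipitation with sequencing was used in whole Caenorhabditis elegans animals to map where SKN-1 tagged with green fluorescent protein sits in the genome. SKN-1 is a transcription factor related to mammalian Nrf2 that is known for its role in oxidative stress and detoxification responses. The labels give a wild-type tagged form (WT) and a gain-of-function form that carries the lax188 allele (GF), and the stated purpose was to compare their binding profiles. Of the 8 labelled samples, 4 were precipitated with a Chromotek GFP reagent, 2 per genotype, and each has a peak list: WT 1, WT 2, GF 1 and GF 2. The 4 samples without antibody have no list and were not analysed here. The labels do not say whether replicates came from separate cultures, so the spread between lists may be technical. The files hold no read counts, so the depth behind each list is unknown. With 2 lists against 2, a two-sided exact p for a difference between genotypes can be no smaller than 0.33.

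Of the regions found by all 4 lists that had a protein-coding gene in a window, 12 were named by the smallest sum of ranks. Regions without such a gene were not ranked here. The region with the best summed rank spanned 7487570 to 7488751 on chromosome IV, at the histone genes his-62, his-60 and his-59, with fold enrichments of 2.64 in WT 1, 3.61 in WT 2, 3.61 in GF 1 and 2.34 in GF 2. A neighbouring region at 7486294 to 7487031 with his-61 also ranked among the first 12. The second region, at 6835480 to 6838516 on chromosome I, lay at ahcy-1, which encodes adenosylhomocysteinase, with folds of 2.36, 2.95, 4.05 and 2.33 in the same order. The fifth lay at Y43B11AR.3 and rps-4 on chromosome IV (7083366 to 7084678; 2.25, 2.72, 4.08 and 2.39), and the sixth at arl-13, rplp-1 and rpl-27A on chromosome I (2068898 to 2070608; 2.34, 2.44, 4.40 and 2.45). The constitutive Hsp70 gene hsp-1 on chromosome IV (17278490 to 17281496; 3.13, 3.66, 2.68 and 1.80) was the seventh. The remaining 6 regions of this rule lay at egrh-2, C55B7.3 with acdh-1 (an acyl-CoA dehydrogenase gene), W03C9.6, fbxa-221, Y82E9BR.3 and arrd-10. Coordinates are those of the deposited lists, whose processing notes name build ce10, and exons and introns were not assigned. Fold enrichments are the authors' value per peak and carry no replicate error of their own.

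The lists differed in length. WT 1 held 15943 peaks, WT 2 29541, GF 1 25007 and GF 2 905, so that the GF lists differed 27.6-fold and the WT lists 1.85-fold. Peaks covered 5.16 Mb in WT 1, 11.7 Mb in WT 2, 9.61 Mb in GF 1 and 0.336 Mb in GF 2. Median fold enrichment was low in each list, at 1.46, 1.47, 1.55 and 1.51, and 2.84%, 3.41%, 6.86% and 6.30% of the peaks exceeded a fold of 2. The largest fold was 4.23 in WT 1, 6.2 in WT 2, 5.48 in GF 1 and 2.95 in GF 2. The peak names inside the WT 2 list carry the replicate 1 label of WT although its peaks differ from those of WT 1, so which library it was called from rests on the sample record alone.

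**Figure D1:**
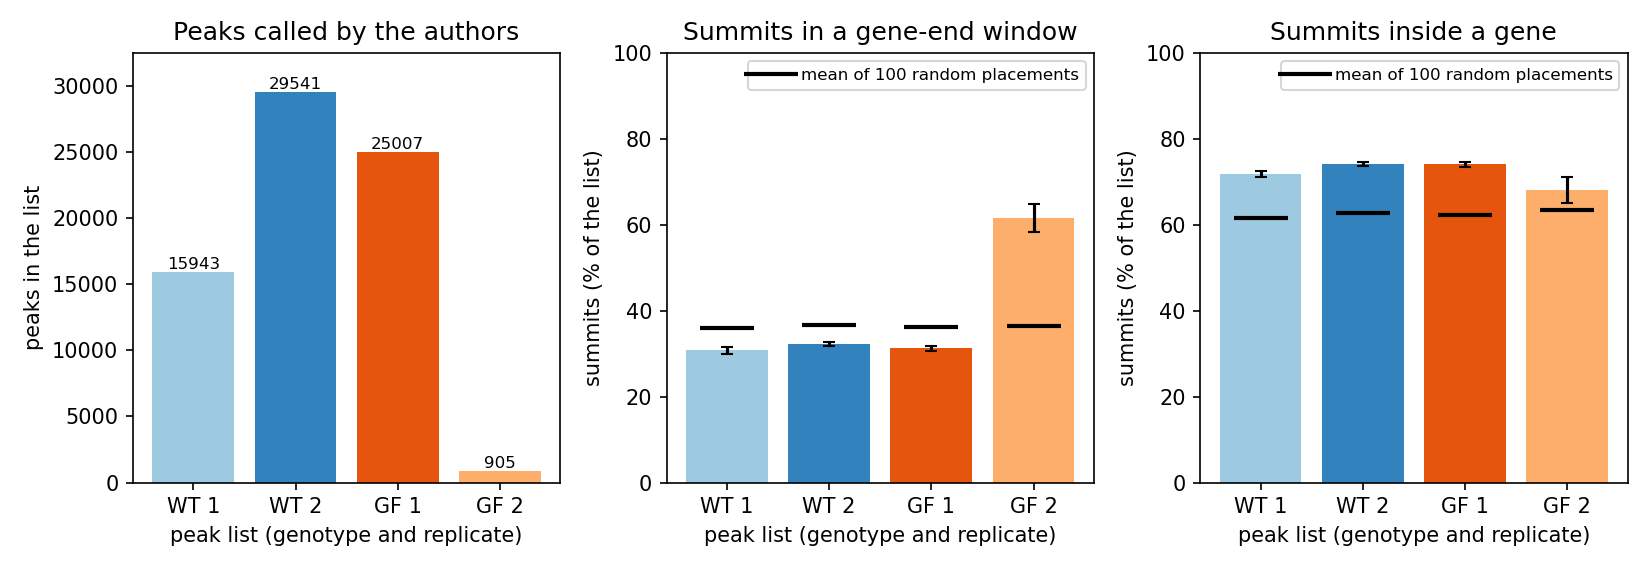
Left, number of peaks per list (15943, 29541, 25007 and 905). Middle and right, percent of peak summits in a window at either end of a protein-coding gene and inside a protein-coding gene, with 95% Wilson intervals as error bars and the mean of 100 random placements as black lines; GF 2 alone lies above random at gene ends (61.7% against 36.5%).

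Replicate lists of a genotype were compared by the peaks of the shorter list. In WT, 13554 of the 15943 WT 1 peaks (85%, Wilson 95% interval 84.5 to 85.6) overlapped a WT 2 peak by at least 1 bp, against 20.5% after random placement. In GF, 660 of the 905 GF 2 peaks (72.9%, 69.9 to 75.7) overlapped a GF 1 peak, against 18.4% at random. Random placement ignores that peaks favour certain parts of the genome. With a reciprocal overlap of 50% the numbers fell to 9184 in WT and 349 in GF, and with summits within 100 bp to 9711 and 398.

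The overlap between genotypes was measured on the reproducible peaks. Of the 660 reproducible GF peaks, 486 (73.6%, 70.1 to 76.9) overlapped a reproducible WT peak, against 9.77% at random, and 613 (92.9%) overlapped a peak of at least 1 WT list. The share of 73.6% fell to 51.3% with a reciprocal overlap of 50% and 47.7% with summits within 100 bp, and was 44.7% without GF 2, 56.9% without GF 1 and 89.7% without WT 1. Of the 13554 reproducible WT peaks, 11905 (87.8%) overlapped a peak of at least 1 GF list, but only 463 (3.42%, 3.12 to 3.74) a reproducible GF peak, a share capped by the 905 peaks of GF 2. Without GF 2 this share was 87.6%. Merging the 4 lists gave 35430 regions, of which 454 were in all 4 lists, 10461 in WT 1, WT 2 and GF 1 but not GF 2, and 13877 in 1 list only. A missing peak is a missing call and was not taken as missing binding.

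The 35 regions in both GF lists and no WT list included ubc-25 with the neighbouring proteasome subunit gene pas-5 at 10565310 to 10565629 on chromosome I, where the fold was 3.84 in GF 1 and 1.61 in GF 2. They also included F34H10.5 (chromosome X, 9637819 to 9638000; 1.94 and 1.96), the profilin gene pfn-1 (chromosome I, 12923369 to 12923933; 1.72 and 1.55), imp-3 with the splicing factor gene rsp-6 (1.85 and 1.45), and tufm-1, a mitochondrial translation elongation factor gene (1.70 and 1.58). Among regions with a protein-coding gene in a window, the other 5 of the 10 with the highest mean fold lay at spig-18, tpxl-1, tebp-2, nud-1 and lsm-1. Both WT lists and no GF list held 1491 regions. Those with a protein-coding gene in a window were led by the nuclear hormone receptor gene nhr-291 at 15320827 to 15321367 on chromosome V, with folds of 2.25 in WT 1 and 3.67 in WT 2. The next was at F44E5.4 and F44E5.5, heat-inducible Hsp70 family genes (chromosome II, 11759333 to 11759613; 1.76 and 3.31). The other 8 lay at Y41E3.13, T08G3.13, ZC262.7, C54E10.3, F55B11.5, the chemoreceptor gene sre-46, W03F11.5 and F47G3.3. Median folds in these regions were 1.42 and 1.44 in the WT lists and 1.54 and 1.46 in the GF lists. These regions describe the lists and were not tested between genotypes.

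With the strongest 905 peaks of each, the mean likeness of lists was about the same within and between genotypes. The 3 splits of the lists are too few to show a difference or its absence. The Jaccard index, the shared part of the joint base pairs, was 0.32 between WT 1 and WT 2 and 0.11 between GF 1 and GF 2, a mean of 0.217. Between genotypes it was 0.31 for WT 1 with GF 1, 0.38 for WT 2 with GF 1, 0.10 for WT 1 with GF 2 and 0.066 for WT 2 with GF 2, a mean of 0.214. The difference of 0.0033 was reached by 2 of the 3 splits of the lists (one-sided exact permutation p = 0.667). It turned negative when WT 1, WT 2 or GF 2 was left out, with values of -0.108, -0.094 and -0.022, and was 0.237 without GF 1.

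**Figure D2:**
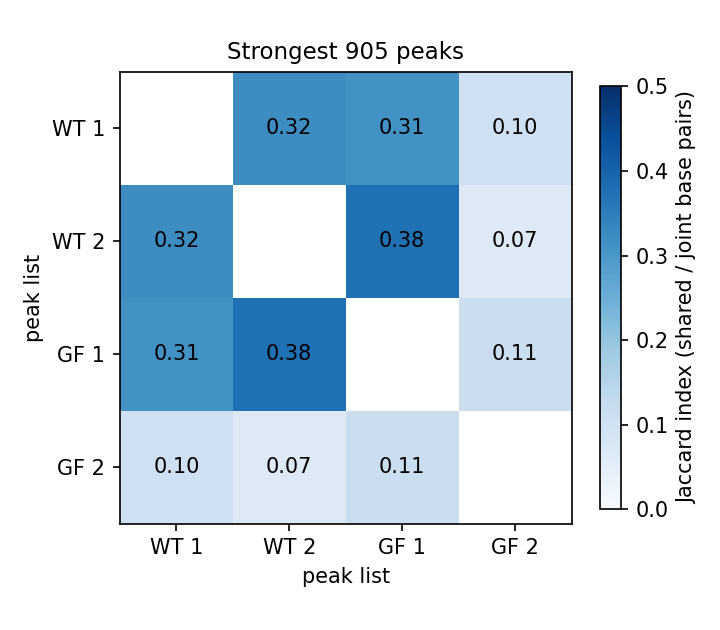
Jaccard index of base pairs between each pair of lists shortened to their strongest 905 peaks by fold. WT 2 and GF 1 are the most alike pair (0.38), and the 3 pairs with GF 2 lie between 0.07 and 0.11.

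Genes for cytosolic ribosomal proteins were bound more often than other genes in each of the 4 lists. This was also so when whole genes were compared within classes of gene length (65, 72, 72 and 68 of 75 in WT 1, WT 2, GF 1 and GF 2). A summit within 1000 bp outside to 200 bp inside either gene end was found at 50 of these 75 genes in WT 1 (Fisher exact odds ratio 5.62, adjusted p = 6.1e-12), 60 in WT 2 (4.74, adjusted p = 2.1e-08), 65 in GF 1 (10.2, adjusted p = 7.0e-16) and 62 in GF 2 (117, adjusted p = 3.2e-71). Among them 43 were bound in all 4 lists, led by rpl-27A, rps-4, rpl-38 (2.35, 2.27, 3.62 and 2.29) and rpl-31 (2.19, 1.79, 3.71 and 2.2). At gene ends 4 were bound in both GF lists and no WT list: rpl-3, rps-10, rpl-19 and rps-11. Peaks elsewhere in these genes are not counted there. When each list was shortened to its strongest 905 peaks, 10 ribosomal protein genes were bound in WT 1, 7 in WT 2, 27 in GF 1 and 62 in GF 2. GF 1 held more of them than WT 1 (19 bound in GF 1 alone, 2 in WT 1 alone, exact McNemar adjusted p = 0.0031) and than WT 2 (22 against 2, exact McNemar adjusted p = 0.0012). GF 2 in turn held more than GF 1, the other list of its genotype (36 against 1, exact McNemar adjusted p = 2.5e-08). Such a gap thus also occurred within a genotype. These tests over genes compare single lists and do not adjust for the genes of any kind bound at that length. Those numbered 383, 352, 448 and 842 in WT 1, WT 2, GF 1 and GF 2. A difference between genotypes was not tested.

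Gene groups were tested in each list with a two-sided Fisher exact test against the other genes among 19971 protein-coding genes, with Benjamini-Hochberg adjustment over 138 tests of 23 groups in 6 sets, the 4 lists and the genes bound in both lists of a genotype. Over the 4 lists, 26 of 92 tests passed an adjusted p of 0.05, and 28 passed when adjusted over the list alone. Genes are not replicates, so each p describes 1 list. In total 5269 genes were bound in WT 1, 9168 in WT 2, 7790 in GF 1 and 842 in GF 2, 4394 in both WT lists, 610 in both GF lists and 380 in all 4.

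Muscle structure genes and C-type lectin genes, the latter often linked to immune responses, were bound more often than other genes in the 3 long lists. Of 42 muscle genes, 23 were bound in WT 1 (odds ratio 3.39), 35 in WT 2 (5.91) and 31 in GF 1 (4.42), with adjusted p of 6.6e-04, 7.4e-06 and 4.8e-05 by Fisher's exact test. GF 2 held 1 of them, the actin gene act-2, which was in all 4 lists (1.57, 1.75, 2.01 and 1.66). Of 239 C-type lectin genes, 89, 154 and 150 were bound in WT 1, WT 2 and GF 1 (odds ratios 1.67, 2.15 and 2.67), and 5 in GF 2 (0.48, Fisher exact adjusted p = 0.24). Among lectin genes clec-80 was bound in all 4 lists, and clec-92, clec-93, clec-108 and clec-5 were among 6 bound in both WT lists and no GF list. Over the strongest 5000 peaks the odds ratios of muscle genes were 2.14, 2.24 and 2.16, not past the threshold. C-type lectins kept all 3 calls there (44, 46 and 47 genes, odds ratios 2.08, 2.29 and 2.27). In lists shortened to 905 peaks, C-type lectins kept the call in GF 1 (13 genes, 2.55) and lost it in WT 1 (4, 0.869) and WT 2 (7, 1.70), and muscle genes had 1, 0 and 0 bound, too few to read, since 1.92%, 1.77% and 2.25% of other genes were bound there. C-type lectins lost all 3 calls with a narrower window of 500 bp outside and 100 bp inside. At a -log10 q of at least 5, WT 1 had 2 groups bound more often, against 3 with all peaks. Ribosomal protein genes kept their call there, so muscle genes, lectin genes or both lost it.

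Chemoreceptor families, 1280 genes expressed mostly in sensory neurons, were bound less often than other genes in each list, with 251, 487, 407 and 10 genes bound in WT 1, WT 2, GF 1 and GF 2 (odds ratios 0.66, 0.71, 0.71 and 0.17, adjusted p of 5.9e-08, 5.6e-08, 2.8e-07 and 1.9e-12). UDP-glucuronosyltransferase genes, which encode conjugating enzymes of detoxification, were bound less often in WT 1 (6 of 67, odds ratio 0.27), WT 2 (12, 0.26) and GF 1 (15, 0.45), with adjusted p of 0.0030, 1.3e-05 and 0.020, and GF 2 held none of the 67 (Fisher exact adjusted p = 0.26). Cytochrome P450 genes were bound less often in WT 2 (21 of 74, odds ratio 0.47, Fisher exact adjusted p = 0.0095) and not past the threshold in WT 1 (12), GF 1 (20) or GF 2 (1). With lists shortened to 905 peaks none of these calls passed in WT 1, WT 2 and GF 1. Chemoreceptors then had odds ratios of 0.888, 0.831 and 0.570, while UDP-glucuronosyltransferases had 0 of 67 bound in each and P450 genes 1, 0 and 0 of 74, groups too small for the test to pass at that length. The P450 call in WT 2 also ended with the wider window (55 genes), the nearest gene end (39), a -log10 q of at least 5 (15), length classes (47) and the strongest 5000 peaks (4), with odds ratios of 1.05, 0.998, 0.557, 0.685 and 0.541 in that order, the third and the fifth near the 0.47 of all peaks. P450 genes passed as bound less often in GF 1 with length classes (33, odds ratio 0.440) and the narrower window (2, 0.105). The UDP-glucuronosyltransferase call ended in WT 1 and GF 1 with the narrower window (4 and 6, odds ratios 0.421 and 0.374) and the strongest 5000 peaks (1 and 2, 0.137 and 0.281), in WT 2 and GF 1 with the nearest gene end (27 and 24, 0.603 and 0.669), and in GF 1 with length classes (35, 0.555). Over the strongest 5000 peaks the odds ratios of UDP-glucuronosyltransferases in WT 1 and GF 1 were lower than over all peaks. The calls of that group lost there show no weaker depletion. Chemoreceptors did weaken there in WT 1 and GF 1, from 0.66 and 0.71 over all peaks to 0.811 and 0.827. The chemoreceptor call ended there in both of these lists. WT 2 kept that call, with an odds ratio of 0.712 against 0.71 over all peaks.

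In GF 2, the short list, 6 further groups were bound more often than other genes. These were proteasome subunits (15 of 32, odds ratio 20.4, Fisher exact adjusted p = 1.0e-11), mitochondrial respiratory chain genes (15 of 42, 12.8, adjusted p = 9.8e-10), germline markers (14 of 49, 9.22, adjusted p = 7.9e-08), heat shock and unfolded protein response genes (8 of 32, 7.64, adjusted p = 2.3e-04), histone genes (11 of 72, 4.14, adjusted p = 9.6e-04) and RNA interference genes (7 of 52, 3.56, adjusted p = 0.021). Neighbouring histone genes share summits in GF 2, such as his-59 with his-60 and his-61 with his-62. The histone test counts such genes as separate, so its p is too small by an unknown amount. Nuclear hormone receptor genes were bound less often (1 of 269, Fisher exact adjusted p = 9.3e-04). In WT 1, WT 2 and GF 1 in that order, bound members numbered 9, 18 and 17 for the proteasome, 16, 28 and 21 for the respiratory chain, 6, 22 and 14 for germline markers, 8, 16 and 9 for heat shock, 21, 26 and 23 for histones, 11, 24 and 15 for RNA interference and 67, 120 and 87 for nuclear hormone receptors. With these windows only the respiratory chain in WT 2 passed the test among these (odds ratio 2.36, Fisher exact adjusted p = 0.028), and its call ended in the strongest 905 peaks. Among those, GF 1 passed for heat shock (4 genes) and histone genes (7). With all peaks of GF 1 these groups had odds ratios of 0.611 and 0.733 without a call. Neighbouring histone genes share peaks in GF 1 too, so the limit on the histone test holds there. The nearest gene end gave lower binding of histone genes in WT 1, WT 2 and GF 1. At 905 peaks each, 842 genes of any kind were bound at an end in GF 2, against 383, 352 and 448 in WT 1, WT 2 and GF 1. The McNemar tests do not adjust for this background. GF 2 had more genes bound at an end than each other list for the proteasome, germline and respiratory chain groups (exact McNemar adjusted p at most 0.0096). For heat shock, histone and RNA interference genes no such pair passed (exact McNemar adjusted p from 0.13 to 0.94). With whole genes in length classes, proteasome subunits passed as bound more often in WT 1, WT 2 and GF 1 too (20, 28 and 28 genes, odds ratios 2.41, 3.61 and 5.03), and in WT 2 and GF 1 also with the wider window (30 and 28). Length classes also gave calls for heat shock genes in WT 1 (22, 2.52) and germline markers in WT 2 (44, 3.52), and lower binding of histone genes and nuclear hormone receptors in WT 2 and GF 1.

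Members of these groups are named by summits in the windows at gene ends, and peaks elsewhere in a gene are not counted. The proteasome subunit genes rpn-11, pas-6, pas-1 and pbs-5 were among 5 bound in all 4 lists, and pas-5 and pas-3 were bound in both GF lists and no WT list. Respiratory chain genes bound in all 4 lists numbered 6, led by ant-1.1, an adenine nucleotide translocator gene (2.52, 1.42, 2.80 and 2.29), and cyc-2.1, a cytochrome c gene (1.69, 1.98, 2.09 and 2.29). The Hsp90 gene hsp-90 (2.34 in GF 1 and 1.42 in GF 2) and the mitochondrial chaperone gene hsp-6 (1.41 and 1.42) were bound at an end in both GF lists and no WT list, and the small heat shock genes hsp-16.2 and hsp-16.41, which share a window, in both WT lists only (1.40 and 1.44). Of germline markers, syp-4 was bound in all 4 lists (1.80, 2.25, 3.27 and 1.96), pgl-3, htp-1 and deps-1 in both GF lists and no WT list, and htp-2 and htp-3 in both WT lists and no GF list. In the RNA interference group, the exonuclease gene xrn-2 was bound in all 4 lists (2.02, 2.21, 2.78 and 2.14), while alg-1, eri-5, rsd-2 and nrde-3 were among 5 bound in both WT lists and no GF list. Of histone genes, 7 were bound in all 4 lists, and near-identical copies and shared windows make single histone genes uncertain. With the narrower window the GF 2 calls ended for histone genes (6 bound, odds ratio 3.2) and RNA interference genes (2 bound, odds ratio 1.4), which left 5 groups bound more often. The GF 2 call for nuclear hormone receptors ended with the nearest gene end (3 bound) and at a -log10 q of at least 5 (1 bound). The second loss came in a shorter list with the same number bound as with all peaks.

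Phase II detoxification and glutathione genes, a class of known SKN-1 targets, passed the test in no list. Of 43, 8 were bound in WT 1, 18 in WT 2, 14 in GF 1 and 2 in GF 2 (odds ratios 0.64, 0.85, 0.75 and 1.11, adjusted p from 0.52 to 0.88), and none in all 4 lists. The 9 further groups without a call in the 4 lists had these numbers of bound genes in WT 1, WT 2, GF 1 and GF 2. Glutathione S-transferases (49 genes) had 16, 29, 23 and 3, with gst-26 in all 4 lists. Antioxidant enzymes (29) had 4, 7, 8 and 1, and genes of SKN-1 regulation and signalling (37) had 5, 20, 17 and 2. Innate immune genes (55) had 16, 34, 30 and 3, and lipid metabolism genes (65) had 23, 37, 30 and 3, with acdh-1 in all 4 lists. Intestine markers (28) had 6, 9, 8 and 0, and cuticle collagens and hypodermal genes (41) had 17, 20, 15 and 0. Genes of ASI and other sensory neurons (52) had 15, 25, 21 and 1, and pan-neuronal genes (27) had 9, 12, 6 and 1. Some of these groups passed as bound more often under other settings. Glutathione S-transferases did so in WT 2 over the strongest 5000 peaks (11, odds ratio 2.75, against 2.05 in WT 1 and 2.36 in GF 1 without a call) and with summits moved 100 bp down, and in WT 1 with the wider window. Lipid metabolism genes did so with length classes in WT 2 (59, 3.46) and GF 2 (11, 3.54) but not in WT 1 or GF 1, with the nearest gene end in WT 1, GF 1 and GF 2, and with the wider window in GF 2. Cuticle collagens did so with length classes and the nearest gene end in WT 1, WT 2 and GF 1, with the wider window in WT 1 and WT 2, and in WT 1 with the narrower window and with summits moved 100 bp down. Innate immune genes did so in WT 2 at a -log10 q of at least 5, and sensory neuron genes in WT 1 with the nearest gene end.

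**Figure D3:**
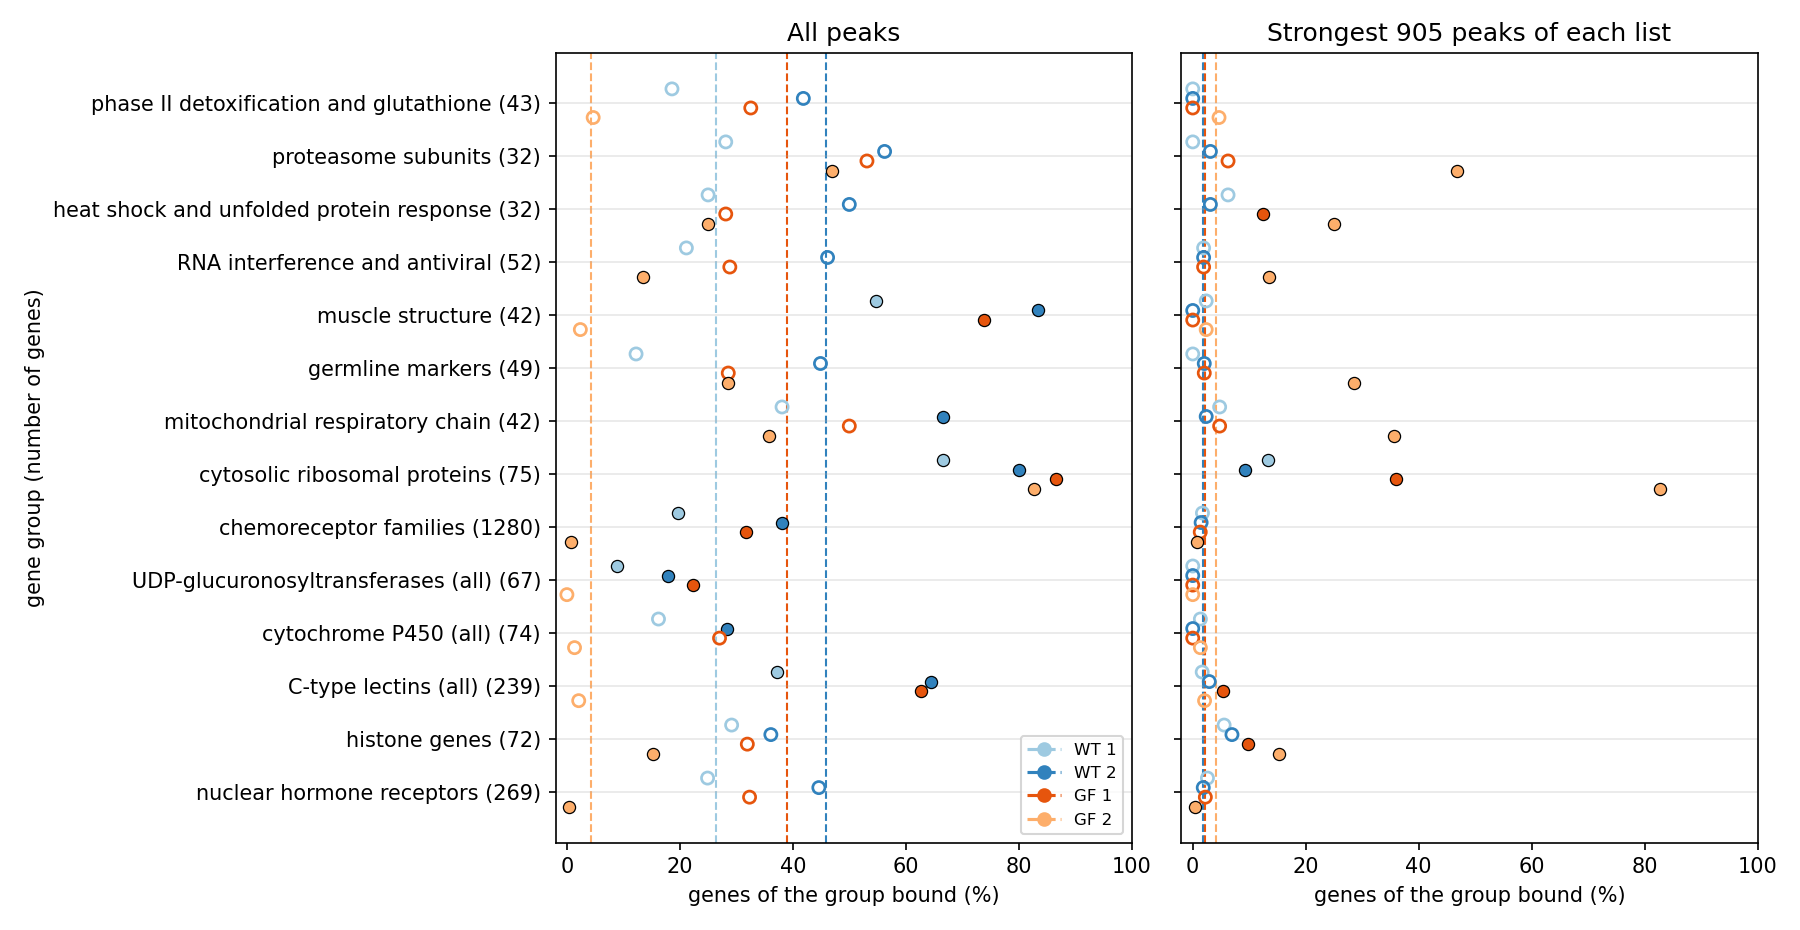
Percent of the genes of each group with a summit at a gene end in each list (x axis), with all peaks (left) and with the strongest 905 peaks of each list (right). Filled points passed the Fisher test at an adjusted p of 0.05, open points did not, and dashed lines give the share among other genes in the list of that colour; ribosomal protein genes (66.7%, 80%, 86.7% and 82.7% with all peaks) lie right of the dashed line in each list, and phase II detoxification genes have open points throughout.

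Of 8 genes chosen before the data were examined, 7 had a peak in at least 1 list. The glutathione S-transferase gene gst-4, a widely used SKN-1 reporter target, had no summit in it or within 1000 bp of it in any list. The gene gcs-1, which encodes a subunit of glutamate-cysteine ligase, had its strongest peak at 9037162 to 9037541 on chromosome II in WT 2 (fold 1.56, -log10 q 8.47) and at 9037166 to 9037621 in GF 1 (1.54, 5.52), with none in WT 1 or GF 2, and gst-10 had 1 peak, in WT 2 (1.37). The Dicer-related helicase gene drh-1 had 1 peak in WT 2 (1.29) and 1 in GF 1 (1.57, chromosome IV, 6610455 to 6610717), and the Dicer gene dcr-1 had peaks only in WT 2 (up to 1.47). At daf-7, a TGF-beta ligand gene expressed in ASI neurons, peaks reached 1.35 in WT 1, 1.87 in WT 2 (chromosome III, 812558 to 813655) and 1.81 in GF 1 (812758 to 813650), and GF 2 had none. The skn-1 gene itself held 4, 6 and 7 summits in or near it in WT 1, WT 2 and GF 1 (highest folds 1.48, 1.67 and 1.76) and none in GF 2. The gene of its repressor WDR-23, wdr-23, had 2 in WT 2, 1 in GF 1 and 2 in GF 2 (1.5, 1.52 and 1.64) and none in WT 1. In a list of GF 2's length, a missing peak at any of these genes carries little weight.

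Summits lay inside genes more often than random placement gave, and at gene ends more often only in GF 2. Inside protein-coding genes lay 71.9% of summits in WT 1, 74.2% in WT 2, 74.1% in GF 1 and 68.2% (65.1 to 71.1) in GF 2, against 61.7%, 62.7%, 62.3% and 63.5% at random. In the windows at gene ends lay 30.8% (30 to 31.5), 32.3% (31.8 to 32.8) and 31.3% (30.7 to 31.9) in WT 1, WT 2 and GF 1, below the 36%, 36.7% and 36.3% of random placement, and 61.7% (58.4 to 64.8) in GF 2, against 36.5%. Among the strongest 905 peaks the shares were 32.8%, 30.5% and 36.9% in WT 1, WT 2 and GF 1. The gene table gives no strand, so windows cover both ends of a gene and do not separate promoters from 3' ends.

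Chromosome X, with 13.7% of the protein-coding genes, held 21.8% of the peaks in WT 1 (exact binomial 95% interval 21.1 to 22.4), 12% in WT 2 (11.7 to 12.4), 16% in GF 1 (16 to 17) and 7.07% in GF 2 (5.49 to 8.94). The ranges of both genotypes overlapped, and a difference between them was not tested. Among the strongest 905 peaks these shares were 13.9%, 5.08%, 6.74% and 7.07%. Chromosome V, with 25% of the genes, held fewer peaks than its share of genes in each list, at 18.2%, 21.1%, 19.6% and 19.3%, and chromosome I held 15.1%, 16.8%, 16% and 20% against 14.4% of the genes. The direction depends on the baseline. Chromosome X has 17.7% of the length, above the share of GF 1 peaks there, and chromosome V 20.9%, not above that of WT 2.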

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

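Length classes of genes, summits moved by 100 bp, the strongest 5000 peaks, and the strongest 905 peaks for reproducible peaks, gene ends and chromosome X were chosen after the data were seen. The depth of the libraries is unknown, so it limits each count of peaks in a way that could not be measured, and the cause of the changes below was not tested unless stated. Merging changed no list, since no 2 peaks of a list overlap. The planned motif search was not run. Over 23 gene groups and 6 sets, the call stayed as it was in 128 of 138 tests with a -log10 q of at least 5, 124 with the wider window, 123 with the narrower one, 114 with the nearest gene end, 113 with the strongest 905 peaks, 137 with summits moved 100 bp up and 134 with 100 bp down, 115 with length classes, and in 59 of 69 with the strongest 5000 peaks of the long lists. Ribosomal protein genes kept their call in each set under each of these settings.

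With a -log10 q of at least 5 and 10, WT 1 held 7759 and 2380 peaks, WT 2 18607 and 7227, GF 1 14426 and 5254, and GF 2 500 and 246, by construction fewer. Reproducible peaks numbered 6468 in WT and 382 in GF at a -log10 q of 5, and 493 and 174 between lists of 905 peaks. They numbered 9184 in WT and 349 in GF with a reciprocal overlap of 50%, and 9711 and 398 with summits within 100 bp. With only 1 list left, the WT set ranged from 15943 (without WT 2) to 29541 (without WT 1) and the GF set from 905 (without GF 1) to 25007 (without GF 2). The share of reproducible GF peaks at a reproducible WT peak was 51.3% with reciprocal overlap and 47.7% with summits within 100 bp, and ranged from 44.7% (without GF 2) to 89.7% (without WT 1), with 56.9% without GF 1. The reverse share was 1.95% and 1.96% with the same overlap rules, 4.0% at a -log10 q of 5, and from 1.84% (without WT 1) to 87.6% (without GF 2), with 3.02% without WT 2, since GF 2 caps it.

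The mean Jaccard difference within minus between genotypes ranged from -0.108 (without WT 1) to 0.237 (without GF 1), was -0.094 without WT 2 and -0.022 without GF 2, and was -0.0749 over the strongest 5000 peaks of the 3 long lists, so its sign changed with single lists. It stayed positive ranked by -log10 q (0.0162) and with the strongest 452 peaks (0.0302), against 0.0033. The share of summits at gene ends over random placement was 0.750, 0.750, 0.765 and 2.25 in WT 1, WT 2, GF 1 and GF 2 with the window of 500 bp outside and 100 bp inside, 0.941, 0.964, 0.947 and 1.3 with 2000 and 500 bp, and 0.893, 0.818 and 0.9996 in WT 1, WT 2 and GF 1 for the strongest 905 peaks. On chromosome X lay 20.9%, 10.4% and 14.7% of the peaks of WT 1, WT 2 and GF 1 at a -log10 q of 5, and 13.9%, 5.08% and 6.74% of their strongest 905.

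Gene groups bound more often than other genes numbered 3 in WT 1, 4 in WT 2, 3 in GF 1, 7 in GF 2, 3 in both WT lists and 6 in both GF lists, and groups bound less often 2, 3, 2, 2, 2 and 2. Higher groups rose to 5 in WT 1 and 5 in both WT lists with the wider window, to 7 in WT 1, 5 in GF 1 and 6 in both WT lists with the nearest gene end, and to 6 in WT 1, 8 in WT 2, 5 in GF 1 and 6 in both WT lists with length classes, where cuticle collagens and proteasome subunits joined in the 3 long lists. They dropped to 1 in WT 1, 1 in WT 2 and 3 in both GF lists with the strongest 905 peaks, to 3 in both GF lists with the narrower window, and ranged from 3 (without GF 2) to 7 (without GF 1) for the GF genotype. Lower groups numbered 4 in GF 1 with the wider window and with length classes. They numbered 0 in WT 1, WT 2, GF 1, both WT and both GF lists with the strongest 905 peaks and 0 in WT 1 and GF 1 with the strongest 5000. They numbered 1 in WT 1, both WT and both GF lists with the narrower window, 1 in GF 2 and both GF lists with the nearest gene end, 1 in GF 2, both WT and both GF lists at a -log10 q of 5, and 1 in both GF lists with length classes or summits moved 100 bp down.

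The odds ratio of a group changed direction with a call on one side in 22 of 1173 repeats. Among the strongest 905 peaks, muscle genes went from 5.91 in WT 2, 4.42 in GF 1 and 4.31 in both WT lists to 0.0, with 0 genes bound where 1.77%, 2.25% and 0.863% of other genes were, too few to read as a direction, and over the strongest 5000 peaks muscle genes had 2.14, 2.24 and 2.16 in WT 1, WT 2 and GF 1. Among the strongest 905 peaks C-type lectins went to 0.869 in WT 1 and 0.971 in both WT lists. There, GF 1 rose to 6.27 for heat shock and 4.75 for histone genes. With the nearest gene end, heat shock genes had 2.85 in WT 1 and 2.98 in both WT lists, cuticle collagens 3.28 in GF 1, germline markers 2.24 in WT 2, lipid metabolism 3.75 in both GF lists, and histone genes 0.441 in WT 1 and 0.423 in both WT lists. With length classes, heat shock genes had 2.52 in WT 1 and 2.44 in both WT lists, cuticle collagens 4.30 in GF 1, germline markers 3.52 in WT 2 and lipid metabolism 3.12 in both GF lists. With the wider window, lipid metabolism had 2.99 in both GF lists and cytochrome P450 1.05 in WT 2, and over the strongest 5000 peaks the respiratory chain had 0.998 in WT 2. In 190 further repeats the odds ratio crossed 1 without a call under either setting.

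As a replicate block, lists with the same number were compared with each other only. Of the GF 1 peaks 48.7% overlapped a WT 1 peak, and of the GF 2 peaks 74.5% a WT 2 peak, while 80.9% of WT 1 peaks overlapped GF 1 and 2.12% of WT 2 peaks GF 2. The Jaccard difference under this pairing was 0.0285. Presence at the merged regions deviated from the genotype means with a correlation of 0.210 between the same-numbered lists, but 2 numbers are too few to show that they pair the samples.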

Other observations

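Apart from the repeat of ribosomal protein genes by q, the tests in this part were chosen after the result was seen. Genes of small nuclear RNAs, the RNA parts of the spliceosome, and of small nucleolar RNAs, which guide RNA modification, lay near few of the strongest peaks. The shares were nevertheless above those of random placement. Of the strongest 905 peaks, 3 in WT 1, 12 in WT 2, 40 in GF 1 and 19 in GF 2 lay within 100 bp of an snRNA gene, which is 0.331% (Wilson 95% interval 0.113 to 0.970), 1.33% (0.760 to 2.3), 4.42% (3.26 to 5.96) and 2.1% (1.35 to 3.26), against at most 0.077% at random. For snoRNA genes the numbers were 10, 9, 29 and 27, or 1.10% (0.601 to 2.02), 0.994% (0.524 to 1.88), 3.20% (2.24 to 4.56) and 2.98% (2.06 to 4.31), against at most 0.133% at random. Both GF intervals lay above both WT intervals there, and for snRNA genes only that of GF 1 did. Over all peaks the snoRNA interval of GF 1 (0.300% to 0.451%) overlapped those of WT 1 (0.168% to 0.320%) and WT 2 (0.221% to 0.341%). The snRNA interval of GF 1 (0.229% to 0.362%) then lay above those of WT 1 (0.0714% to 0.178%) and WT 2 (0.0995% to 0.184%). GF 2 has only 905 peaks, so its values stay the same. A difference between genotypes was not tested. Over all peaks, piRNA genes were near 0.213%, 0.267%, 0.328% and 0.663% of the summits, against 1.86% to 2.5% at random, and tRNA genes near 0.138%, 0.220%, 0.352% and 0.773%, against about 0.15% to 0.18%.

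GF 2 was the short list whose summits lay at gene ends. A candidate explanation is that it is the strongest part of the GF 1 list, shortened by lower depth or enrichment. By fold or by q, no stretch of GF 1 ranks as long as GF 2 and none of 4 strongest parts of GF 1, from 113 to 905 peaks, exceeded 46.02% (37.1 to 55.2) of summits at gene ends. This is below the 61.7% (58.4 to 64.8) of GF 2, which argues against a rank stretch of GF 1 as its source. A shallow or poorly enriched library need not follow the ranks of another list. Lower depth or enrichment as such was therefore not tested, since the lists carry no read counts. Of the strongest 905 GF 1 peaks, 19.2% by fold and 24.2% by q lay at a GF 2 peak. A wrong label within the series could not be told apart from a poor library: the Jaccard index of GF 2 was 0.0099 higher with GF 1 than with the closer WT list, within the spread of 0.0245 over its pairs. Genotype alone does not account for it, since GF 1 has the same one with 25007 peaks and 31.3% (30.7 to 31.9) at gene ends.

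The 3 long lists lay inside genes and overlapped across genotypes, from 48.7% of GF 1 peaks at WT 1 to 80.9% of WT 1 peaks at GF 1. This may be signal at highly expressed genes that does not depend on SKN-1 sites. Ribosomal protein genes were bound more often than others in 4 of 4 lists and phase II detoxification genes in 0, but both were known before this was set as a test, so it decides nothing, and glutathione S-transferases passed in WT 2 over the strongest 5000 peaks. No expression was measured here and the samples without antibody were not analysed here, so this explanation cannot be told apart from shared binding by both forms of SKN-1. Few of these peaks lay near ribosomal RNA or histone genes, at most 0.188% (0.132 to 0.268) of a long list within 1000 bp. Other repeated sequences were not counted here, so repeats as a source stay open.

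At equal list length, more ribosomal protein genes were bound in the GF than in the WT lists: 10 and 7 of 75 in WT 1 and WT 2, 27 and 62 in GF 1 and GF 2. Ranked by q instead of fold, the numbers were 10, 6, 28 and 62, so the lowest GF list exceeded the highest WT list by 18 genes (exact McNemar p at most 1.2e-04, adjusted over 4 tests), which argues against the ranking as the cause. Nor does the short GF 2 list alone carry it, because among the strongest 5000 peaks GF 1 held 55 of these genes, 19 more than the higher WT list (exact McNemar p = 6.6e-05, adjusted over 2 tests). The mean difference of 36 genes was the largest of the 3 splits, with 19 the highest other, too few splits for a share under 0.05, so a difference in depth or enrichment that falls along the genotypes cannot be told apart from one of genotype. The McNemar tests also do not adjust for the genes of any kind bound among the strongest 905 peaks by fold. Those numbered 383 and 352 in WT 1 and WT 2, and 448 and 842 in GF 1 and GF 2. Among the strongest 5000 peaks, other genes bound numbered 1942 in WT 1, 1876 in WT 2 and 1909 in GF 1. That background was thus no higher in GF 1 than in WT 1, where 36 ribosomal protein genes were bound against 55 in GF 1. This covers only 1 GF list. GF 1 and GF 2, lists of the same genotype, also differed at 27 against 62 genes (exact McNemar p = 2.5e-08, adjusted over 138 tests). A small p in these tests therefore does not single out genotype. The genotype stays open as untested.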
